A study of Mus musculus with 8 samples.

How the data were processed

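RNA of whole skin from 8 male mice aged 35 weeks, 5 wild-type and 3 NPY-tet, was sequenced as non-directional libraries after poly-T selection, per the labels. The deposited counts are whole numbers per Ensembl gene, 1 column per mouse, for 56748 genes. The deposited FPKM are, from their values, counts scaled to the gene length in the file and to an effective library size that is constant within a library and is not the column's total. CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mm39 build are named per the submitters' processing notes, which do not state the role of each tool, the filters or the annotation release. Libraries were joined to mice by the column names, which carry the mouse numbers of the sample titles. The library names in the sample descriptions carry a mouse number higher by 1 for samples 3 to 8, with the same genotype. Which mouse stands behind a replicate number is therefore uncertain, whereas the genotype is the same in the titles, descriptions and column names.

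Counts were compared between genotypes with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group (18495 genes kept), TMM size factors, a robust quasi-likelihood fit with genotype as the only term, and a two-sided quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.318. CPM are TMM-scaled and given as mean ± SD over mice. The depth of 31370433 to 47495565 counts per library sets the counting error, and a group with 0 counts was compared with a floor of 3 counts over the group.

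Before the data were examined 45 gene lists (775 symbols, 3 of them not in the file) were fixed for skin cell types, inflammation, fibrosis, lipid metabolism, the NPY system, handling and RNA quality. Of these 44 had at least 5 tested members. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated per list and with fry. Adjustment was over the 44 lists. A list's score is the mean log2 CPM of its members with a prior count of 2, compared by a two-sided exact permutation test over 56 splits, whose smallest p is 0.0179.

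The rule for named genes was also fixed beforehand. It took Npy first, then up to 12 genes in each direction past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes, Rik clones and pseudogenes. Where fewer than 5 passed in a direction, it took the 8 with the smallest p, named as not past the threshold. This was read as keeping the conditions on CPM, overlap and gene type. From each list it took up to 4 members with the smallest p where the list passed and up to 2 otherwise, of which the text gives examples. Genes named outside the rule are Ddx3y and Xist, from the planned check of sex-linked genes. Cabp2, A330044P14Rik, Col1a1, Col3a1, Acta2, Il36g, Oasl1 and Ifit2 and the genes singled out in NPY-tet replicate 1 lie outside it too. These were chosen after their values were seen.

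The alternatives were other size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, limma on log2 FPKM with pseudocounts of 1 and 0.1, an adjusted p under 0.01, a log2 fold change of at least 1, the replicate number as a block, tissue covariates, muscle and hair genes left out, and each library left out in turn. Those chosen after seeing the data were the ribosomal RNA set (boundary 1% of counts) as a covariate or as separate subsets, ribosomal RNA genes left out, and Npy left out of the lists.

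The procedures were tested on simulated data at the same group sizes and dispersion. The edgeR test recovered 8%, 46%, 78% and 86% of 50 genes planted at 1.5-, 2-, 4- and 8-fold, with 5 false calls among 114. DESeq2 recovered 12%, 58%, 86% and 92% with 33 false calls among 157, limma-voom 4%, 42%, 82% and 84% with 5, and limma on FPKM 0%, 24%, 80% and 82% with 4. All 3 list tests recovered 5 of 5 lists of 20 genes planted with a log2 shift of 0.5 and called 0 of 44 unchanged lists, with genes drawn independently of one another, unlike genes in tissue.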

Results

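Poly-A selected RNA from whole skin of 8 male mice was sequenced at 35 weeks of age. The NPY-tet group held 3 mice homozygous for a tetracycline-regulated allele of Npy (strain B6;129S4-Npytm2Rpa/J), and the wild-type group held 5 siblings. Npy encodes neuropeptide Y, a transmitter peptide of sympathetic nerves and brain neurons. The labels pose the question of how overexpression of the peptide relates to inflammation and fibrosis of the skin. Each library is 1 mouse, so the spread between libraries includes the spread between animals. Total counts were 33650102, 40168359, 34385849, 47495565 and 31370433 in wild-type replicates 1 to 5 and 35953372, 32694123 and 34129385 in NPY-tet replicates 1 to 3. Fold changes are given as log2 of NPY-tet over wild-type with their standard error (SE), and expression as mean CPM (counts scaled to library size) ± SD over 5 wild-type or 3 NPY-tet mice. The SE of a gene was derived from its test, as the size of the log2 fold change divided by the square root of the F statistic. Every library carried 725 to 1680 counts of the Y-linked gene Ddx3y and at most 4 counts of Xist, the transcript of the inactive X chromosome, and the sex-linked list had too few expressed members for a set test.

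The libraries fell into 2 sets by their content of ribosomal RNA, a split that the labels do not give. In wild-type replicates 1, 2, 3 and 5 and in NPY-tet replicate 1, ribosomal RNA genes took 6.54% to 8.13% of the counts. In wild-type replicate 4 and NPY-tet replicates 2 and 3 they took 0.0398% to 0.0759% (0.0647% in the wild-type mouse, 95% Wilson interval 0.0640% to 0.0654%, which covers counting error only). The rRNA-rich set thus compared 1 NPY-tet with 4 wild-type mice and the rRNA-poor set 2 NPY-tet mice with 1 wild-type mouse. The split was unbalanced and overlapped in part with genotype, and a test within either set rests on an arm of 1 mouse whose spread is assumed to be that of the other. Score differences within the sets are given below for the lists that passed and for the immune cell lists.

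Npy was the gene that separated the genotypes. It stood at 0.237 ± 0.148 CPM in wild-type skin (5 to 15 counts per library) and at 308 ± 11.6 CPM in NPY-tet skin (10394 to 11864 counts). The log2 fold change was 10.37 (SE 0.28), a ratio of 1323, with an adjusted p of 3.60e-09. The gene (ENSMUSG00000029819) lies on the plus strand of chromosome 6 at 49799690 to 49806487 in the mm39 build, and the counts are for its annotated exons as a whole. The log2 fold change was 10.27 within the rRNA-rich libraries and 10.72 within the rRNA-poor ones.

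**Figure D1:**
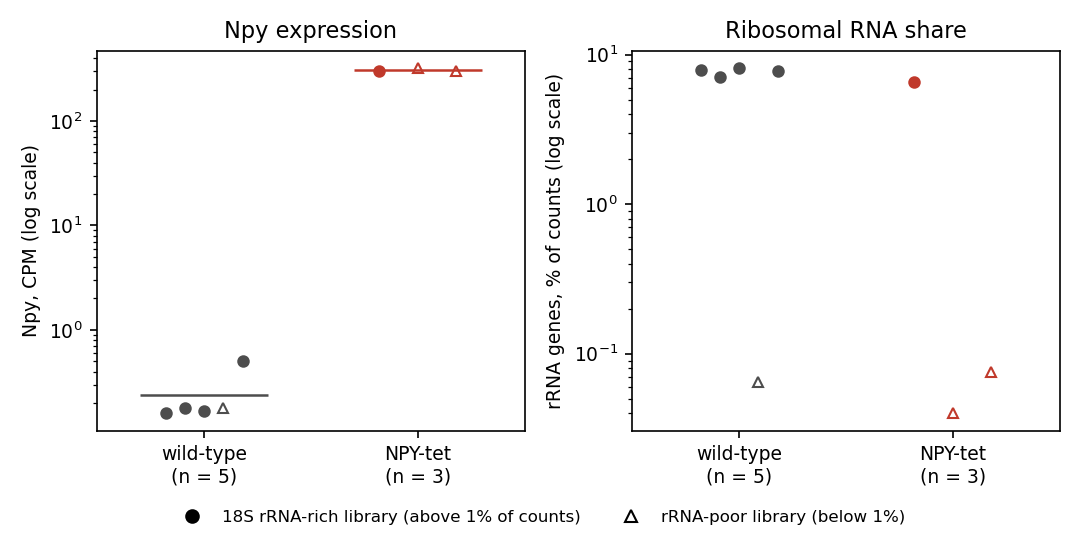
Left, Npy in CPM on a log axis for each library, with the group mean as a line; right, the percent of counts in ribosomal RNA genes on a log axis. The 3 NPY-tet libraries lie at 300 to 322 CPM of Npy and the 5 wild-type libraries at 0.159 to 0.502 CPM, whereas the ribosomal RNA share splits both groups.

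Of the other genes of the NPY system, Pyy, which encodes the related gut peptide YY, had the smallest p. It stood at 4.94 ± 0.871 CPM in wild-type and 1.73 ± 0.732 CPM in NPY-tet skin, with every NPY-tet mouse below every wild-type mouse. Its log2 fold change of -1.51 (SE 0.30) had an adjusted p of 0.346 over all genes and of 0.00133 adjusted over the list alone. By DESeq2 Pyy passed over all genes. The receptor gene Npy1r stood at 5.43 ± 1.10 and 4.61 ± 1.34 CPM. The list of NPY peptides, receptors and processing enzymes passed the set test toward higher expression (adjusted p = 1.99e-12; adjusted p = 0.0108 with an estimated correlation), but 4 of its 8 tested members were higher and 4 lower. Its median of -0.04 had the opposite sign to the test. The call ended with limma-voom and with limma on FPKM, and with Npy left out, an alternative chosen after the data were seen, the list pointed downward (median -0.11; adjusted p = 0.0640). Its score differed by 0.81 in the rRNA-rich and 1.09 in the rRNA-poor set. By edgeR 1 member passed over all genes, Npy, and adjusted over the list alone 2 did, Npy and Pyy. The median moved to -0.09, -0.01 and -0.13 without wild-type replicate 3, NPY-tet replicate 1 or NPY-tet replicate 2. The sympathetic neuron list, which also holds Npy, passed as well (median 0.29, or 0.09 without NPY-tet replicate 1; adjusted p = 6.68e-39, and 0.000426 with an estimated correlation). Its score differed by 2.69 and 2.08 within the sets, differences that Npy itself enters. Its median lay below 0 by DESeq2, with no filter on low counts and in the rRNA-poor libraries alone (-0.020 in the last), with the test still pointing upward. Its markers other than Npy did not pass, with Th, the rate-limiting enzyme of catecholamine synthesis, at 2.25 ± 1.83 and 5.29 ± 3.91 CPM and the noradrenaline transporter Slc6a2 at 22.2 ± 5.92 and 26.3 ± 7.85 CPM.

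Beyond Npy, no gene passed an adjusted p of 0.05 among the 18495 tested by the quasi-likelihood test of edgeR, so 1 gene was higher and 0 were lower. At an unadjusted p under 0.05 there were 1106 genes, 450 higher and 656 lower. In 14 of the 56 splits of the libraries into 5 and 3, the real one included, there were at least as many (up to 3425). By other tools DESeq2 called 61 genes, 19 higher and 42 lower, limma-voom called 3, all higher, and limma on FPKM called 1. With the ribosomal RNA set as a covariate, an alternative chosen after the data were seen, 11 genes passed, 9 higher and 2 lower. The 8 higher ones other than Npy all had their highest value in NPY-tet replicate 1. Without NPY-tet replicate 3 the count was 8, 2 higher and 6 lower.

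The genes named next are not past the threshold (adjusted p 0.298 to 0.535). They have the smallest p in each direction among genes with a mean of at least 1 CPM and no overlap between the groups, with the gene types above left out. The lack of overlap was a condition of the choice and is no evidence for these genes. Chance gives 3.57% of genes with no overlap. Those at higher values in every NPY-tet than in every wild-type mouse were Serpina3j, a serine protease inhibitor gene of a multicopy cluster (29.1 ± 3.52 and 90.9 ± 48.0 CPM), the immediate early transcription factor gene Fos (25.8 ± 5.33 and 94.2 ± 42.7 CPM) and the very long chain fatty acid elongase gene Elovl3 (29.4 ± 5.50 and 55.6 ± 14.0 CPM). The others were the wax ester synthase gene Awat1 (15.6 ± 4.21 and 31.5 ± 5.77 CPM), Wdfy1, Lyve1, Pnpla5 and Tnfrsf12a. Those at lower values in every NPY-tet mouse were the antiviral helicase gene Ddx60 (4.61 ± 0.265 and 1.85 ± 0.350 CPM) and the interferon-inducible GTPase genes Igtp (30.4 ± 8.61 and 13.5 ± 0.988 CPM), Irgm2 (56.2 ± 14.2 and 27.1 ± 3.08 CPM) and Irgm1 (20.9 ± 2.12 and 12.7 ± 1.31 CPM). Lower as well were the chemokine genes Cxcl9 (5.14 ± 1.86 and 1.40 ± 0.393 CPM) and Ccl21a (45.8 ± 5.10 and 24.9 ± 6.12 CPM), and the leukocyte cytoskeletal genes Myo1f and Lcp1 (104 ± 9.03 and 66.5 ± 7.40 CPM for the latter). Serpina3j, Ccl21a and the immunity-related GTPases have near-identical relatives, and how reads were shared among them is uncertain. By DESeq2 the genes named in this paragraph passed over all genes, apart from Pnpla5 and Tnfrsf12a. A further gene, Cabp2 on chromosome 19, was chosen after its values were seen. It had 0 counts in all 5 wild-type libraries and 34 to 55 counts in each NPY-tet library. This was at least 75.2-fold higher against a floor of 3 counts over the wild-type group. Its adjusted p was 0.0798 by edgeR, and it passed by DESeq2, by limma-voom, with no filter on low counts and with the white adipocyte covariate.

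Across the 44 gene lists that could be tested, 19 passed the camera test with a preset correlation of 0.01, 10 toward higher and 9 toward lower expression. With the correlation estimated per list 2 passed, the NPY list and the sympathetic neuron list, and both hold Npy. In 15 of the 56 ways of splitting the 8 libraries into 5 and 3, the real one included, at least 19 lists passed with the preset correlation. With the ribosomal RNA set as a covariate 24 lists passed with the preset correlation, and 2 with an estimated one, again the NPY and sympathetic neuron lists. The calls of basal keratinocytes (median 0.15; adjusted p = 0.352) and skeletal muscle (-0.20; 0.147) ended. Those gained were T cells (-0.29; 0.0331), B and plasma cells (-0.57; 0.0240), collagen processing, lymphatic endothelium, melanocytes, cholesterol synthesis and proliferation, and with an estimated correlation none of these 7 passed.

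Interferon-stimulated genes were the group of genes that stood lowest in NPY-tet skin. All 24 tested members had lower fitted values, with a median log2 fold change of -1.10, and the list passed camera (adjusted p = 1.65e-24; adjusted p = 0.176 with an estimated correlation). By edgeR 0 members passed over all genes, 17 had an unadjusted p under 0.05, and 15 were lower when adjusted over the list alone. By DESeq2 Gbp2, Zbp1 and Oas1a passed over all genes, as did Gbp2 with no filter and Zbp1 with the ribosomal RNA set as a covariate (adjusted p 0.0317). Among these the guanylate-binding protein Gbp2 fell from 43.2 ± 9.14 to 19.6 ± 6.19 CPM and the nucleic acid sensor Zbp1 from 11.4 ± 2.99 to 3.59 ± 1.69 CPM. The oligoadenylate synthetase Oas1a fell from 7.14 ± 3.62 to 2.30 ± 0.527 CPM. The list's score, the mean log2 CPM of its members, was 2.98 ± 0.50 in wild-type and 1.97 ± 0.34 in NPY-tet mice, with all 3 NPY-tet mice below all 5 wild-type mice (two-sided exact permutation p = 0.0357, and 0.262 after adjustment over the lists). Within the rRNA-rich libraries the score differed by -1.22 and within the rRNA-poor ones by -1.48. The first difference rests on NPY-tet replicate 1, which had the lowest score (1.60). The second rests on wild-type replicate 4, which had the highest (3.64). Gbp, Oas and Ifit genes are families with similar members, so single values within them are uncertain.

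**Figure D2:**
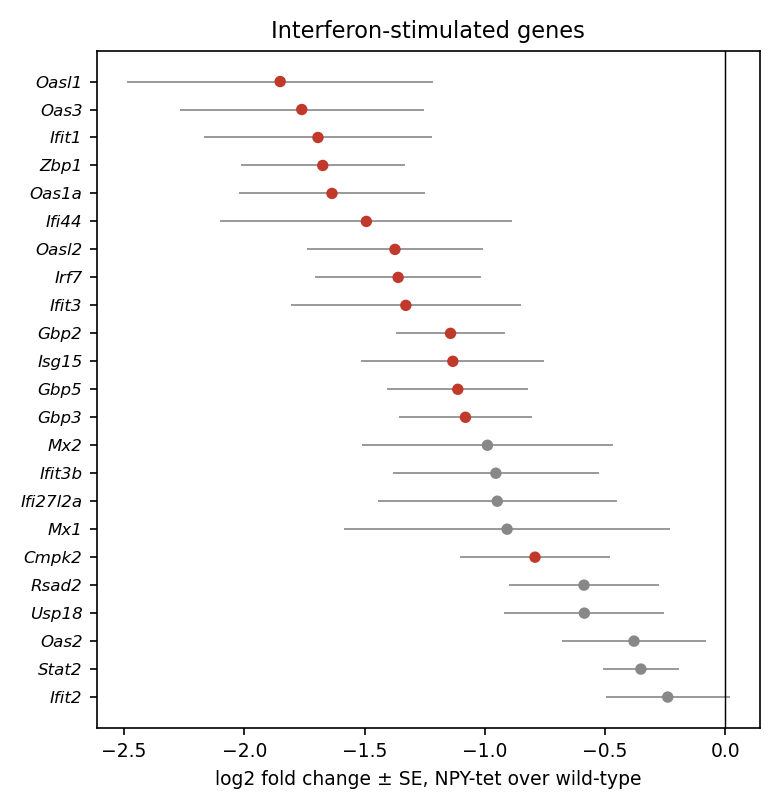
Log2 fold change with SE of 23 of the 24 interferon-stimulated genes, NPY-tet over wild-type (3 and 5 mice). Red points mark the 14 genes drawn that are past an adjusted p of 0.05 over the list alone; all points drawn lie below 0, from -1.85 for Oasl1 to -0.24 for Ifit2.

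Among immune cell markers, the macrophage and monocyte list and the dendritic and Langerhans cell list were lower in NPY-tet skin. Macrophage markers had a median of -0.34 (adjusted p = 0.000283; adjusted p = 0.329 with an estimated correlation), and without NPY-tet replicate 2 the median was -0.24 and the adjusted p 0.0711. Adjusted over the list alone 4 of the 20 fell, among them Folr2, a folate receptor of resident macrophages (12.5 ± 1.94 to 6.15 ± 2.66 CPM), Cd68 (52.9 ± 11.4 to 30.7 ± 10.6 CPM) and the Fc receptor gene Fcgr1 (7.47 ± 3.08 to 3.79 ± 0.773 CPM). A further 2 rose, among them Lyve1 (10.3 ± 2.64 to 21.9 ± 6.03 CPM), which lymphatic endothelium also expresses. Markers of dendritic and Langerhans cells had a median of -0.27 (adjusted p = 0.00119; adjusted p = 0.332 with an estimated correlation) and 0 of 15 passed over the list alone. The class II genes H2-Aa stood at 536 ± 129 and 353 ± 75.4 CPM and Cd74 at 1389 ± 299 and 897 ± 235 CPM. The macrophage score was 3.67 to 4.13 in NPY-tet and 4.16 to 4.42 in wild-type mice, without overlap. Its two-sided exact permutation p was 0.0179, and 0.157 after adjustment over the lists. Within the rRNA-rich and rRNA-poor sets the macrophage score differed by -0.15 and -0.53 and the dendritic cell score by -0.27 and -0.52. The macrophage call ended in the rRNA-rich libraries alone and the dendritic cell call with the replicate block.

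The remaining immune lists did not pass in the fit without covariates, and most of them differed between the ribosomal RNA sets in sign or size. The median was -0.15 for T cells (adjusted p = 0.106), -0.12 for dendritic epidermal gamma-delta T cells (0.209), -0.44 for B and plasma cells (0.106), -0.13 for neutrophils, where the test pointed upward (0.819), and 0.14 for mast cells (0.844). Without NPY-tet replicate 1 all 5 passed toward lower expression, with medians of -0.33, -0.16, -0.50, -0.50 and -0.21. T cells did so without wild-type replicate 3 (-0.20), and B and plasma cells did so without wild-type replicates 2 or 3 or NPY-tet replicate 3 (-0.67, -0.53 and -0.69). Within the rRNA-rich and rRNA-poor sets the scores differed by 0.27 and -1.08 for T cells, 0.14 and -0.81 for gamma-delta T cells, and -0.08 and -1.06 for B and plasma cells. They differed by 1.26 and -0.48 for neutrophils and 0.65 and -0.14 for mast cells. T cells and B and plasma cells passed toward lower expression with the set as a covariate (adjusted p = 0.0331 and 0.0240), but not with an estimated correlation (adjusted p = 0.654 and 0.472). Single members passed adjusted over the list alone: S100a9 among neutrophil markers, which was higher, Fcer1g, a signalling chain of Fc receptors in the gamma-delta T cell list (35.9 ± 5.25 to 22.8 ± 1.92 CPM), and the mast cell protease gene Mcpt4 (70.8 ± 6.17 to 48.2 ± 7.32 CPM). The rise of S100a9 rested largely on NPY-tet replicate 1, at 5.15 CPM against 1.33 and 0.692 in the other NPY-tet mice.

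Genes of inflammation went in different directions. Type 17 and antimicrobial genes were higher, with a median of 0.47 (adjusted p = 0.000356; adjusted p = 0.374 with an estimated correlation) and 5 of 10 members past the threshold over the list alone. Among them Nfkbiz, a nuclear regulator of NF-kB target genes, rose from 16.1 ± 4.80 to 32.9 ± 11.0 CPM and S100a9, a calgranulin, from 0.582 ± 0.269 to 2.39 ± 2.41 CPM. The set call rested on NPY-tet replicate 1, without which the median was 0.15 and the adjusted p 0.0650. The score differed by 1.27 in the rRNA-rich set, which holds that mouse, and by 0.11 in the rRNA-poor set. The call also ended in the rRNA-poor libraries alone and with the white adipocyte covariate. Complement and acute-phase genes were lower (median -0.41; adjusted p = 3.05e-05; adjusted p = 0.502 with an estimated correlation) with 0 of 17 past the threshold over the list alone. The complement gene C3 stood at 1141 ± 345 and 691 ± 280 CPM and the protease C1s1 at 199 ± 24.1 and 139 ± 17.1 CPM. Without NPY-tet replicate 2 that median was -0.16 (adjusted p 0.101) and without NPY-tet replicate 3 it was -0.62. Its score differed by -0.21 in the rRNA-rich and -0.74 in the rRNA-poor set. The call ended with the hair shaft covariate, and with the white adipocyte covariate the test pointed upward without passing. Inflammatory cytokines and chemokines did not pass (median -0.12; adjusted p = 0.0783), though they did without wild-type replicate 2, wild-type replicate 3 or NPY-tet replicate 1 (-0.24, -0.19 and -0.19). Over the list alone Cxcl9 and Ccl21a fell and the epithelial cytokine gene Il36g rose. Type 2 and itch-related genes did not pass (median -0.03; adjusted p = 0.303), with the lipoxygenase gene Alox15 lower over the list alone (2.01 ± 0.704 to 0.665 ± 0.164 CPM).

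Collagens and other fibrous matrix genes were not higher in NPY-tet skin. The list had a median of -0.07 with 8 members higher and 16 lower. It passed toward lower expression (adjusted p = 0.0192; adjusted p = 0.739 with an estimated correlation) and had 0 of 24 members past the threshold over the list alone. The call ended without wild-type replicate 1 (median -0.05), wild-type replicate 5 (0.02) or NPY-tet replicate 1 (0.11). The median reached -0.27 without NPY-tet replicate 2, -0.43 without NPY-tet replicate 3, -0.13 without wild-type replicate 2 and -0.12 without wild-type replicate 3. NPY-tet replicate 1 had a score of 6.45, against 7.70 and 7.85 in the other NPY-tet mice and 7.31 to 8.07 in wild-type mice. The score differed by -1.19 in the rRNA-rich and 0.31 in the rRNA-poor set. The call also ended by DESeq2, by limma-voom, with the replicate block and with the skeletal muscle covariate, and it turned upward in the rRNA-poor libraries alone. Fibronectin, Fn1, stood at 681 ± 170 and 375 ± 239 CPM and the microfibril gene Fbn1 at 128 ± 28.7 and 91.4 ± 38.3 CPM. Chosen after their values were seen, Col1a1 and Col3a1, the main fibrillar collagens of dermis, had log2 fold changes of -0.00 (SE 0.82) and -0.03 (SE 0.70), and the myofibroblast actin gene Acta2 one of 0.01 (SE 0.15). Fibroblast markers were lower (median -0.25; adjusted p = 0.000890; adjusted p = 0.502 with an estimated correlation; 0 of 17 over the list alone). Their median was -0.12 (adjusted p 0.365) without NPY-tet replicate 1, -0.14 without wild-type replicate 4 and -0.39 without NPY-tet replicate 3. Their score differed by -0.79 and -0.26 within the sets, and the call ended with the white adipocyte covariate. Collagen processing genes (median -0.12; adjusted p = 0.172, but -0.37 and past the threshold without NPY-tet replicate 3), TGF-beta and myofibroblast genes (0.06; 0.655), matrix proteases and their inhibitors (-0.08; 0.653) and cellular senescence genes (0.01; 0.424) did not pass.

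White adipocyte markers were lower in NPY-tet skin, all 20 of them, with a median of -0.41 (adjusted p = 1.38e-10; adjusted p = 0.332 with an estimated correlation). Over the list alone 1 passed, Adrb3, the beta-3 adrenergic receptor gene (61.8 ± 13.3 to 33.2 ± 3.39 CPM). The adipokine gene Retn stood at 121 ± 24.7 and 69.6 ± 29.5 CPM and the adipocyte transcription factor Pparg at 48.4 ± 13.0 and 32.7 ± 4.15 CPM. The median was -0.16 with the hair shaft covariate, -0.25 without NPY-tet replicate 2 and -0.84 without NPY-tet replicate 3, whose score of 8.83 lay within the wild-type range of 8.48 to 8.99. The score differed by -0.75 in the rRNA-rich and -0.58 in the rRNA-poor set. Genes of fatty acid and triglyceride synthesis were lower too (median -0.28, or -0.14 without NPY-tet replicate 1; adjusted p = 0.00283; adjusted p = 0.374 with an estimated correlation; 0 of 18 over the list alone), with Fasn at 1042 ± 136 and 664 ± 283 CPM. Their score differed by -0.61 and -0.13 within the sets, and the call ended in the rRNA-poor libraries alone and with the white adipocyte covariate. Thermogenic adipocyte markers (0.13; 0.153, past the threshold at 0.21 without wild-type replicate 3) and cholesterol synthesis genes (-0.05; 0.558) did not pass, with Elovl3 the 1 member of the former past the threshold over the list alone. Cholesterol synthesis passed upward at 0.14 without NPY-tet replicate 1 and downward at -0.13 without NPY-tet replicate 2.

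Sebaceous gland genes went the other way. Their median was 0.44 (adjusted p = 9.00e-08; adjusted p = 0.176 with an estimated correlation), and over the list alone 8 of 16 rose and 1, Pparg, fell. Elovl3 and Awat1 were among them, together with the desaturase gene Scd3 (69.4 ± 14.1 to 106 ± 9.69 CPM) and the wax synthesis gene Dgat2l6 (3.58 ± 1.89 to 13.7 ± 8.49 CPM). The score was 6.12 ± 0.14 in wild-type and 6.54 ± 0.19 in NPY-tet mice, with all NPY-tet above all wild-type mice (two-sided exact permutation p = 0.0179, the smallest that 56 splits allow, and 0.157 after adjustment over the lists). It differed by 0.60 in the rRNA-rich and 0.16 in the rRNA-poor set, where the call ended.

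Basal keratinocyte markers were higher (median 0.18; adjusted p = 0.0213; adjusted p = 0.502 with an estimated correlation; 0 of 13 over the list alone), and the call ended without wild-type replicates 2 or 3 or NPY-tet replicate 3 (0.15, 0.11 and 0.20), with the ribosomal RNA set or skeletal muscle as a covariate, and in each set alone. Their score differed by 0.17 and 0.049 within the sets. Differentiating keratinocyte genes did not pass (0.04; 0.212), although Hrnr, a cornified envelope gene, rose over the list alone (35.0 ± 5.43 to 57.7 ± 12.5 CPM), and the list passed without wild-type replicate 4 (0.15) or NPY-tet replicate 1 (0.08). Stress keratins and barrier alarm genes were higher (0.24; adjusted p = 0.0307; adjusted p = 0.734 with an estimated correlation; 0 of 12 over the list alone), with medians of 1.31 without wild-type replicate 5 and 0.55 without NPY-tet replicate 3. Leaving out any other library ended the call, at -0.11 to 0.16. So did DESeq2, the stricter filter, the skeletal muscle covariate and the rRNA-rich libraries alone, and the hair shaft and white adipocyte covariates turned it downward. The score was 2.44 ± 1.203 in wild-type and 3.26 ± 0.90 in NPY-tet mice and differed by 1.26 and 1.16 within the sets.

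Hair follicle genes differed widely between single mice, and the width of the wild-type range rested on wild-type replicate 5. Hair shaft keratins and associated proteins had a median of 0.59 (adjusted p = 3.22e-05; adjusted p = 0.704 with an estimated correlation). For growth-phase inner root sheath and matrix genes it was 0.37 (adjusted p = 0.000800; adjusted p = 0.716 with an estimated correlation). Over the list alone 0 of 22 and 0 of 20 passed. The hair shaft score ran from -2.84 to 5.87 among wild-type and from 1.03 to 5.28 among NPY-tet mice. Apart from wild-type replicate 5, wild-type scores reached at most 0.58, below every NPY-tet mouse. Without wild-type replicate 5 the 2 medians were 5.75 and 3.72. Without NPY-tet replicate 2 they were -0.76, with the test still pointing upward, and -0.08, where the call ended. They were 1.08 and 0.81 without NPY-tet replicate 3, and without any other single wild-type mouse they were 0.27 to 0.32 and 0.12 to 0.19. The hair shaft score differed by 3.31 in the rRNA-rich and 5.76 in the rRNA-poor set, and the growth-phase score by 2.65 and 4.01. The fitted medians gave another picture in the rRNA-rich libraries alone, at -0.26 for hair shaft and 0.24 for growth-phase genes. In the rRNA-poor libraries alone they were 8.96 and 4.72. Both calls ended by DESeq2 and in the rRNA-rich libraries alone, and with the white adipocyte covariate both tests pointed downward without passing, as did that of growth-phase genes with the hair shaft covariate. Follicle stem cell genes (0.16; 0.558, past the threshold at 0.17 without wild-type replicate 5) and melanocyte genes (0.45; 0.0603) did not pass. Melanocyte genes did pass without wild-type replicate 5 (1.89), NPY-tet replicate 1 (0.63) or NPY-tet replicate 3 (0.71).

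**Figure D3:**
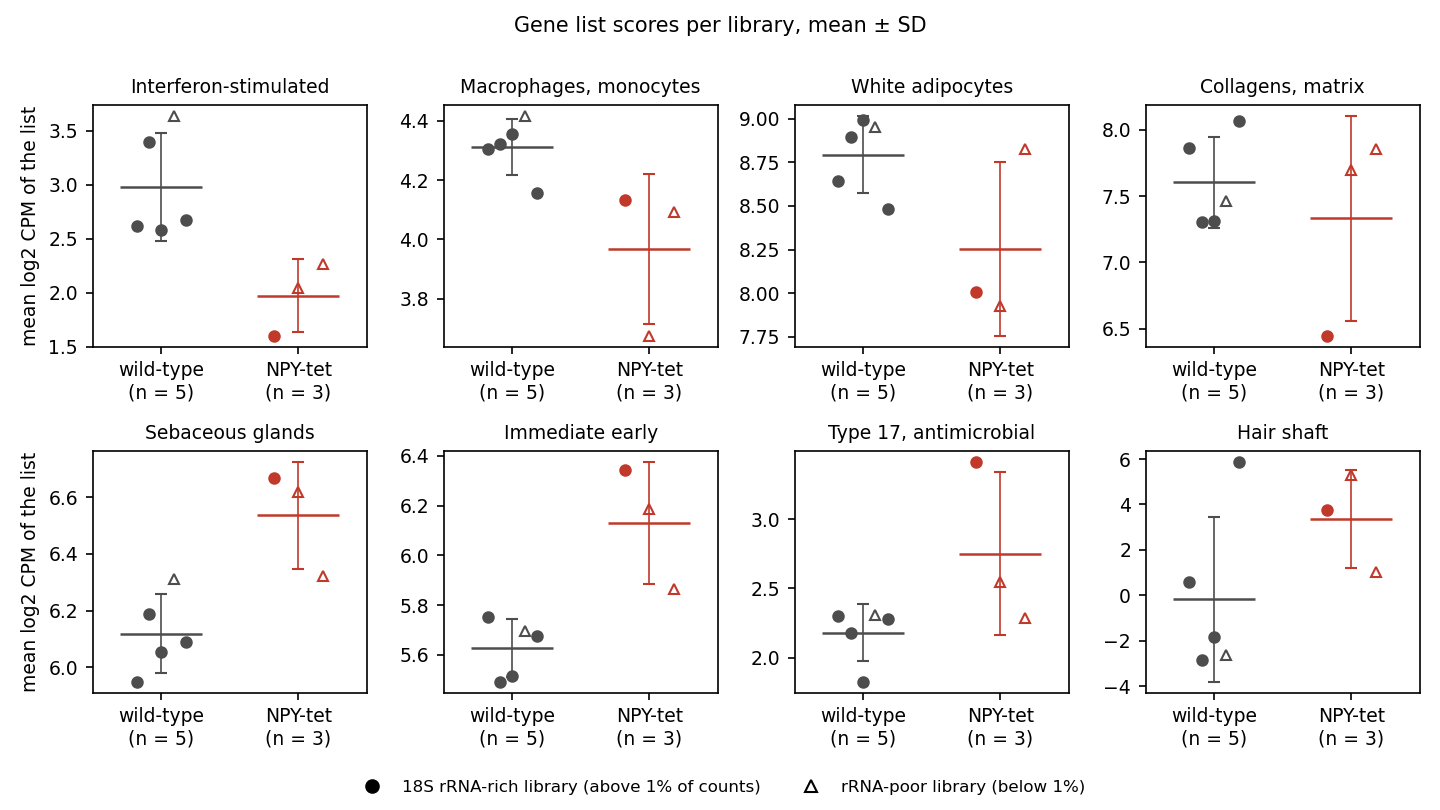
Score of 8 gene lists (mean log2 CPM of the members) for each library, with the group mean as a line and the SD as a bar; filled circles are rRNA-rich and open triangles rRNA-poor libraries. All 3 NPY-tet mice lie below all wild-type mice for interferon-stimulated genes (1.60 to 2.27 against 2.58 to 3.64), whereas the hair shaft score ranges from -2.84 to 5.87 within wild-type mice.

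Skeletal muscle markers, which may come from the panniculus muscle under the skin, were lower (median -0.35, adjusted p = 0.000284, adjusted p = 0.704 with an estimated correlation, 0 of 25 over the list alone). Without wild-type replicate 3 the median was -0.15 and the adjusted p 0.0525, and the score differed by -1.12 in the rRNA-rich and 0.67 in the rRNA-poor set, where the test turned upward. The call also ended with the ribosomal RNA set or white adipocytes as a covariate. Smooth muscle and pericytes (-0.02; 0.653), blood endothelium (-0.11; 0.272), lymphatic endothelium (0.32; 0.359), Schwann cells and nerve (-0.13; 0.106), proliferation (0.01; 0.378) and red blood cells (0.13; 0.355) did not pass. Over the list alone Lyve1 was higher and Ccl21a lower among lymphatic markers. Of these, blood endothelium passed without NPY-tet replicate 1 (-0.24) and nerve without wild-type replicate 4 or NPY-tet replicate 1 (-0.17 and -0.20). Proliferation passed upward without NPY-tet replicate 1 (0.35) and downward without NPY-tet replicate 2 (-0.45), and red blood cells without NPY-tet replicate 2 (0.32).

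Of the lists that track handling and RNA quality, immediate early genes alone passed the set test. Immediate early genes, which respond within minutes to stimuli and tissue handling, were higher (median 0.41, or 0.25 without NPY-tet replicate 1; adjusted p = 1.38e-10; adjusted p = 0.176 with an estimated correlation), and 5 of 17 rose over the list alone. Egr1 stood at 55.1 ± 17.1 and 125 ± 34.7 CPM and Zfp36 at 63.2 ± 4.23 and 89.4 ± 17.2 CPM. All NPY-tet scores lay above all wild-type scores (6.13 ± 0.24 and 5.63 ± 0.12; two-sided exact permutation p = 0.0179, and 0.157 after adjustment over the lists), by 0.74 in the rRNA-rich and 0.33 in the rRNA-poor set. Glucocorticoid and stress-hormone targets were higher (median 0.31; adjusted p = 9.94e-05; adjusted p = 0.332 with an estimated correlation; 0 of 12 over the list alone), with Fkbp5 at 89.0 ± 14.1 and 136 ± 38.5 CPM. Their score differed by 0.86 in the rRNA-rich set, which holds NPY-tet replicate 1 alone of its genotype, and by 0.039 in the rRNA-poor set, where the call ended. Circadian clock genes (0.03; 0.759), mitochondrially encoded genes (-0.12; 0.640, past the threshold at -0.21 without wild-type replicate 4) and cytosolic ribosomal proteins (0.00; 0.869) did not pass.

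The tet allele was made in embryonic stem cells of a 129 strain, so the region around Npy was examined on its own. Within 10 Mb on each side of the gene, 1 of 137 tested genes was past the threshold, Npy itself, and 0 of the 136 others by edgeR. At an unadjusted p under 0.05 there were 9 of those 136 (6.62%) and 1096 of 18358 elsewhere (5.97%), an odds ratio of 1.12 with a 95% interval of 0.498 to 2.19 (two-sided Fisher's exact test, p = 0.715).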

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

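Tests chosen only after the result was seen were those of the ribosomal RNA set, of immune cell content and of a single library behind the interferon pattern, and that of the spread between mice behind the hair pattern.

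In the wild-type group 1 library stood apart from the other 4 in 21 of 189 values compared (11.1%), where chance gives about 1 in 20. The values are not independent of one another. The NPY-tet group, with 3 mice, was not examined this way. Wild-type replicate 4 had a ribosomal RNA share of 0.0647% against 7.07% to 8.13% in the other wild-type libraries, a share of 8.27% of counts in its 10 most abundant genes (95% Wilson interval 8.26% to 8.28%) against 16.3% to 18.3%, and 757 CPM of the class II gene H2-Aa against 435 to 529. Wild-type replicate 3 had 22006 genes detected against 24547 to 24982, a type 17 and antimicrobial score of 1.83 against 2.18 to 2.31, and 157 CPM of mt-Atp6 against 11.2 to 22.2.

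Wild-type replicate 5 stood apart in the remaining 15. Its stress keratin score was 4.56 and its proliferation score 3.49. For hair and pigment genes it had, in CPM, 62.4 of Krtap8-1, 66.0 of Krtap15, 83.3 of Krt33b, 35.0 of Krt32, 27.6 of Msx2, 11.6 of Lef1, 20.7 of Kit and 1.30 of Slc24a5. For other genes it had 37.1 CPM of Krt16, 1.505 of Fbn2, 1.505 of S100a8, 89.1 of Lox and 0.502 of Npy. For Npy the other wild-type libraries had 0.159 to 0.180 CPM and the NPY-tet libraries 300 to 322 CPM.

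The first pattern weighed is the hair shaft list, higher in NPY-tet mice with a median of 0.59. In 42 of the 56 splits of the 8 libraries the median was as far from 0, so chance cannot be excluded: the other splits ran from -8.36 to 5.93. The score ranged over 8.70 log2 units among wild-type mice, against a difference of 3.52 between the genotype means. Wild-type replicate 5, at 5.87, set that range. The other wild-type mice lay at -2.84 to 0.58, below all NPY-tet mice at 1.03 to 5.28, so the comparison rests on that mouse. Differences between single mice, whichever their genotype, are therefore a candidate explanation. The growth phase of the hair is a biological difference between mice that the labels do not give, and it was not tested.

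The second pattern is the interferon-stimulated list, with a median of -1.10. It was as far from 0 in 1 of the 56 splits, the real one, and the other splits ran from -1.02 to 1.07. For this list taken alone the real split was thus the most extreme by the median, at the smallest share that 56 splits allow. By the list's score it was not, with a two-sided exact permutation p of 0.0357, above the smallest possible 0.0179. The list was singled out from 44, and its score had an exact permutation p of 0.262 after adjustment over the lists. With 56 splits no list could pass that adjustment on its own, so the adjusted value cannot decide. Chance cannot be excluded. With the ribosomal RNA set as a covariate the median did not shrink but was -1.49. In both sets, however, 1 genotype is a single mouse. These are NPY-tet replicate 1, with the lowest interferon score of all (1.60), and wild-type replicate 4, with the highest (3.64). The adjusted fit leans on these 2 mice, so it cannot exclude the set as the cause. The tables argue against a single library, since the highest median without 1 library was -0.91. A lower content of immune cells cannot be told apart from lower expression per cell. The median of 51 T cell, macrophage and dendritic cell markers was -0.28, above that of the interferon list by 0.82 (SE 0.147). This SE is over genes, taken as independent of one another, and does not cover the spread between mice. Per library, the interferon score minus the marker score was -0.62 ± 0.38 in wild-type and -1.34 ± 0.45 in NPY-tet mice (two-sided exact permutation p = 0.0536). The genotype may lower interferon-stimulated expression, as a hypothesis, and exposure of the mice to infection, litter and cage stay open and were not tested. The interferon score ranged over 1.06 log2 units among wild-type mice, against a difference of -1.01 between the genotype means. Differences between single mice thus stay open as well, although all NPY-tet mice lay below all wild-type mice. Handling and tissue makeup stay open too, since other lists separated the same mice. The immediate early score was 5.86 to 6.34 in NPY-tet and 5.49 to 5.75 in wild-type mice (two-sided exact permutation p = 0.0179), all 20 white adipocyte markers were lower and sebaceous genes were higher. The macrophage score was lower in all NPY-tet than in all wild-type mice, with the same permutation p of 0.0179. With the white adipocyte covariate the interferon median was -0.68.

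The third pattern is the number of calls. At least 1 gene was called in 4 of the 56 splits, so chance cannot be excluded for a count of 1 taken without regard to which gene it is. This says nothing about Npy, the gene called, at 300 to 322 CPM in NPY-tet and 0.159 to 0.502 CPM in wild-type libraries. The real value was 1, and the highest other was 530, for wild-type replicate 5 with NPY-tet replicates 1 and 2, the 3 libraries with the highest hair shaft scores, which points to a structure of the samples. For the lists, 15 of the 56 splits had at least the real 19 past the threshold with the preset correlation, and the highest other had 22, so chance cannot be excluded for their number.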

How the results depend on the processing

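Alternatives chosen only after the data were seen were the ribosomal RNA set as a covariate, each set alone, ribosomal RNA genes left out and Npy left out of the lists.

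Npy was higher and past the threshold in every alternative run, at log2 fold changes from 8.59 (FPKM with a pseudocount of 1) to 10.81 (replicate block). The count of genes changed, 1 as reported (1 higher, 0 lower), was 21 (9 higher, 12 lower) with no filter, 61 (19 and 42) by DESeq2, 3 (3 higher) by limma-voom, 2 (2 higher) with the replicate block, 36 (2 and 34) with the white adipocyte covariate, 11 (9 and 2) with the ribosomal RNA set as a covariate, 332 (104 and 228) in the rRNA-rich libraries alone and 227 (127 and 100) in the rRNA-poor ones alone. Each set alone holds a genotype with 1 mouse, whose spread is assumed to be that of the other. Without 1 library the count ran from 1 to 8, higher from 1 to 2 and lower from 0 to 6, the upper ends without NPY-tet replicate 3. The cause was not tested. Same-numbered mice of both genotypes correlated at -0.04, -0.11 and 0.30, with own number best for 1 of 3. Replicate numbers 4 and 5 occur only in wild-type mice, so with the block these mice do not enter the genotype comparison. The block raised the genes with an unadjusted p under 0.05 from 1106 to 2029 and the hair shaft median from 0.59 to 5.10. It brought nerve (adjusted p 0.0199), differentiating keratinocytes (0.0216), follicle stem cells (0.00319) and melanocytes (0.000177) past the threshold. Leaving out wild-type replicate 5 alone moved the hair shaft median to 5.75, so the shift with the block does not speak for a pairing of mice.

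The 19 lists past the threshold became 1 with a log2 fold change of at least 1, 2 with an estimated correlation and 2 by fry; in other alternatives they numbered 16 to 27. Without Npy 17 of 43 lists passed with the preset correlation and 0 with an estimated one or by fry. The interferon list was lower, at -1.49 to -0.68, and past the threshold with the preset correlation in each of the 25 alternative fits, but not with an estimated correlation (adjusted p 0.176) or by fry (0.189).

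In these lists the direction of the set test reversed, in some of them with the sign of the median kept, and the cause was not tested. Without NPY-tet replicate 1 the medians were 0.11 for collagens (-0.43 to 0.11 over the libraries left out), -0.50 for neutrophils (-0.50 to 0.070), -0.21 for mast cells (-0.21 to 0.30), 0.14 for cholesterol synthesis (-0.13 to 0.14) and 0.35 for proliferation (-0.45 to 0.35). In the rRNA-poor libraries alone they were 0.16 for collagens, -0.82 for neutrophils, 0.47 for skeletal muscle, 0.45 for proliferation and 0.65 for mitochondrially encoded genes. With the hair shaft covariate they were -0.39 for stress keratins, -0.42 for melanocytes, -0.15 for hair growth-phase genes and -0.20 for follicle stem cells. With the white adipocyte covariate they were -0.024 for complement, -0.81 for stress keratins, -1.31 for melanocytes, -1.76 for hair shaft, -0.92 for hair growth-phase genes, -0.29 for follicle stem cells and 0.12 for ribosomal proteins. Over the alternative fits the medians of the lists past the threshold ran as follows: white adipocytes -0.84 to -0.16, macrophages -0.59 to -0.19, dendritic cells -0.62 to -0.11, fibroblasts -0.61 to -0.10, fatty acid synthesis -0.52 to -0.10, complement -0.68 to -0.024, collagens -1.32 to 0.16, skeletal muscle -0.99 to 0.47, sebaceous glands 0.23 to 0.68, immediate early genes 0.17 to 0.67, glucocorticoid targets 0.20 to 0.62, type 17 genes 0.15 to 1.11, basal keratinocytes 0.041 to 0.26, stress keratins -0.81 to 1.31, hair shaft -1.76 to 8.96, hair growth-phase genes -0.92 to 4.72, sympathetic neurons -0.026 to 0.51 and the NPY list -0.19 to 0.037. Of the other list comparisons 942 kept the direction of the test and the side of the threshold, 91 of them with another sign of the median, 79 became past it and 48 no longer were; of single genes 3451 and 103 did the first and the second.

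Npy itself had 5 to 15 counts per wild-type library. With these group sizes and this dispersion, changes of 1.5-fold were recovered for 8% of simulated genes, so a change of that size in single genes was mostly not detectable. The simulation had 114 calls against 1 in the data, which eases the adjustment, so 8% may be too high for the data. Depth was not varied.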

Other observations

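None of the tests in this part was chosen only after the result was seen; the single-library values were.

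Single genes of NPY-tet replicate 1 were singled out because their values there were high. In CPM it had 13.8 of Ankrd1 (at most 0.623 in the others), 248 of Xirp1, 1280 of Flnc, 144 of Csrp3, 332 of Hspb7, 18.2 of Entpd4b and 10.4 of S100a8, and a collagen score of 6.45 against 7.31 to 8.07 in the others. Its score on the fixed skeletal muscle list was the lowest of the 8 libraries, 8.94 against 9.18 to 10.50, so the muscle genes among these do not stand for that list. Entpd4b has a near-identical neighbour, and how reads were shared between them is uncertain.

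Genes with an unadjusted p under 0.05 could lie near Npy on a segment derived from the 129 strain. Within 10 Mb the odds ratio was 1.12 (95% interval 0.498 to 2.19), whose range includes 1 and reaches past 2, so a linked segment cannot be told apart from none at these numbers.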
